A study of Alcanivorax borkumensis SK2 with 31 samples.

How the data were processed

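Total RNA of the cells was labelled with Cy3 and hybridized to single-colour Agilent arrays, per the labels' protocols. The deposited scanner files hold the intensity of each spot. Per the file headers, they were written by Agilent Feature Extraction 10.7.3.1, which subtracted the background and corrected spatial trends without scaling arrays to each other; the submitters' processing notes name version 10.5.1.1. The deposited value table holds the authors' log2 values of the same arrays. Set against the scanner files, all of its columns but 1 equalled, with an SD of the differences of at most 6.86e-07, the mean log2 processed signal of each probe minus a constant per array that put the 75th percentile within 0.001 of 0, with no centring by gene and all ratios in the same direction. Its column medians ran from -2.08 to -1.00. In the remaining column, hexadecane 15 min replicate 2, 70.0% of the values were whole numbers exactly, with no tolerance, and differed from the scanner values by up to 0.5.

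For each array, log2 of the processed signal was taken for the 15196 gene spots, leaving out 536 control spots and spots flagged as outliers (6 to 26 per array). Saturated spots would have been kept, but there were 0. Spots of a probe were averaged (1598 probes had 1 spot, 6664 had 2 and 27 had 10), the 75th percentile over the 8289 gene probes was subtracted, and the 3 probes of each gene were averaged. Among changed genes, all 3 probes moved the same way in 98.1% to 100% of cases, depending on the comparison. All 2763 genes had a probe well above background on every array of at least 1 group, so the planned filter removed none, and 2725 had one on all 31 arrays. The number of arrays limits the precision. No spiked RNA was used here, so only changes relative to the other transcripts of an array could be measured.

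The 10 groups were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 (values were read with data.table, version 1.17.8), with 21 residual degrees of freedom, and 15 contrasts were taken. All groups share 1 estimate of the spread per gene, so the wide spread of 3 hexadecane groups enters every standard error. A gene was counted as changed when its p adjusted by Benjamini-Hochberg within the contrast was under 0.05 and its change was at least 1 on the log2 scale. Values are given as log2 changes with their standard error from the fit. Named genes followed a rule fixed before the data were examined: the largest rises and falls with an adjusted p under 0.05, a probe well above background on every array of both groups, and, except for differences between responses, every array of one group on the same side of every array of the other. A further condition on the gene's product could not be applied because no names were given, and the first 2 genes by rank in each direction are printed. The rule also names the gene with the largest change of each comparison whatever its other properties. It was outside those ranks for hexadecane at 15 and 30 min, where it is printed in place of the second-ranked rise and the second-ranked fall. For the same reason 24 lists of genes by function, fixed beforehand, could not be matched to the tags and 0 were tested.

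Groups of genes were instead described by time pattern, by overlap between comparisons and by runs of at least 4 consecutive locus tag numbers changed in the same direction, compared with 200 shuffles of the calls over the tags. Correlations and covariances between comparisons with the same controls were set beside 50 simulations of unchanged groups against shared controls, and their shared genes beside the overlap of independent lists, and, for pyruvate, the overlap with 2 different controls for each comparison. The simulated correlation follows from the numbers of arrays whatever the size of the noise, so the covariance is the value to compare. These simulations gave all groups the same spread per gene. The median SD over genes was 0.302 in the hexadecane controls and 0.03 in the pyruvate controls. Noise of shared controls may therefore exceed the simulated covariance with hexadecane and fall below it with pyruvate. Similarity of arrays was measured as the median absolute log2 difference over genes. The fit was tested on simulated data with 200 changed genes among 2763. For pyruvate 60 min against its control it recovered 50% of genes changed by 1 on the log2 scale under both criteria, and 98% of those changed by 1.5 and of those changed by 2. For hexadecane 90 min against its control it recovered 44%, 100% and 100%, with 2 of 2563 unchanged genes called. For the difference in response at 90 min it recovered 42%, 84% and 98%, with 3 called, and for the difference between carbon sources 64%, 98% and 100%, with 1 called. The simulated noise had the same spread in every group, while the real spread differed widely between groups, so these rates need not hold for the real arrays. A change of 1 lies at the minimum itself, which holds down its recovery.

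The alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50, the authors' value table, stricter and looser filters, the median of the probes or the brightest probe, a fit of only the groups compared, another model of the spread, array weights, the slide as a block, controls of the same slide, the replicate number as a block with and without the slide, other thresholds and leaving out each array in turn. Normexp was run on the median spot signal, since the files hold no mean signal. Median centring and the removal of 3 hexadecane arrays together were chosen after the data had been seen. The pyruvate arrays came from 2 slides and the hexadecane arrays from 3 others.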

Results

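Transcript levels of Alcanivorax borkumensis SK2, a marine bacterium that lives on hydrocarbons, were measured on 31 single-colour arrays. The cells had grown exponentially on pyruvate or on hexadecane, a long-chain alkane. They were sampled before and 15, 30, 60 and 90 min after 1-octanol, a membrane-active alcohol, had been added. The labels list no untreated arrays at the later times, so the alcohol and time alone cannot be told apart. The response to the alcohol means here the change from the control taken before it was added. The alcohol was given at 0.66 mM to pyruvate cultures and at 1.64 mM to hexadecane cultures, so carbon source and concentration varied together. The control of pyruvate-grown cells had 4 arrays and each of the other 9 groups had 3. Each array held 15196 gene spots, which gave values for 2763 genes through 3 probes each. The 75th percentile of the signal was 20776 to 24155 in the pyruvate controls and 10690 to 12089 in the pyruvate arrays of 60 min. It was 35234 to 49168 in the hexadecane arrays. At least 97.91% of the gene spots of each array were well above background and 0 were saturated. The files identify genes by locus tag, with 2754 such tags, or by protein accession, and do not pair them with names or functions. Genes are therefore given by locus tag alone, with at most 2 that rose and 2 that fell in each comparison.

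Replicate arrays lay close together in 7 of the 10 groups, where any 2 arrays of a group differed by a median of 0.018 to 0.059 over genes on the log2 scale. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. In the hexadecane control, 15 min and 30 min groups, 3 arrays lay nearer to another label than to their own. The array labelled control replicate 1 differed by 0.023 and 0.045 from the arrays labelled 15 min replicates 1 and 2, and by 0.511 and 0.521 from the other hexadecane controls. The array labelled 15 min replicate 3 differed by 0.043 and 0.046 from 30 min replicates 1 and 2. That labelled 30 min replicate 3 differed by 0.029 and 0.057 from control replicates 2 and 3. All comparisons were made with the arrays as labelled. Counts and named genes of the hexadecane comparisons are followed by their values with these 3 arrays left out, a choice made after the data had been seen.

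**Figure D1:**
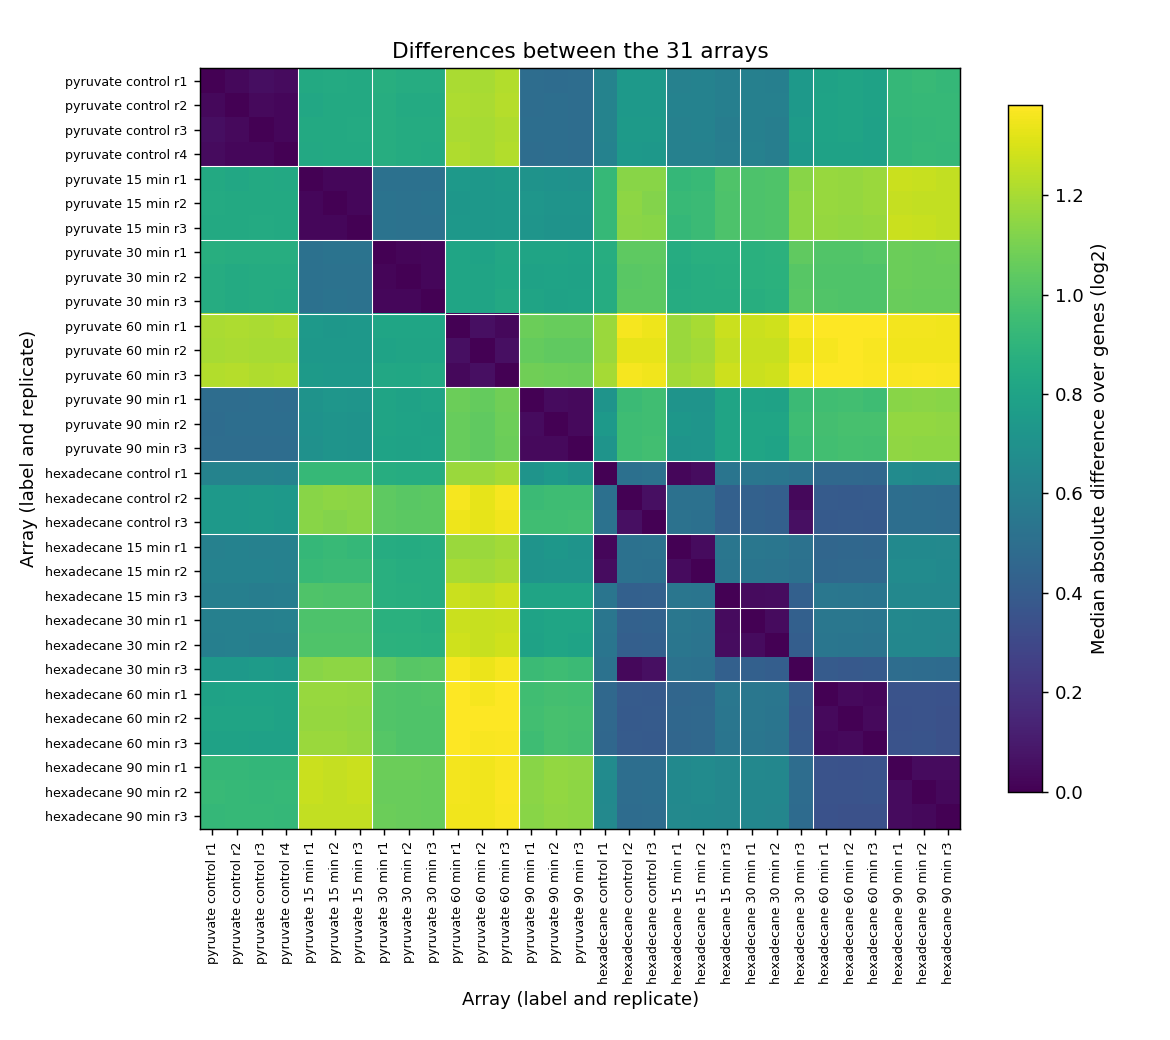
Median absolute difference over 2763 genes (log2) between every pair of the 31 arrays, which are ordered by label along both axes with white lines between groups. Dark blocks off the diagonal show control replicate 1 beside 15 min replicates 1 and 2, 15 min replicate 3 beside 30 min replicates 1 and 2, and 30 min replicate 3 beside control replicates 2 and 3 of the hexadecane arrays.

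The first question was which transcripts changed in pyruvate-grown cells after the alcohol was added. At 15 min, 384 genes rose and 769 fell (3 arrays against 4 controls; limma, adjusted p under 0.05 and a change of at least 1 on the log2 scale). ABO_2685 rose by 6.86 ± 0.28 (SE) on the log2 scale, 116-fold, with an adjusted p of 5.3e-17, and ABO_2431 by 6.83 ± 0.33, with an adjusted p of 1.7e-15. Among the falls, ABO_2620 fell by 4.07 ± 0.24 (adjusted p of 1.2e-13) and ABO_2532 fell by 3.93 ± 0.21 (adjusted p of 1.4e-14). Of the 1150 changed genes with a locus tag, 274 stood in runs of at least 4 consecutive tag numbers that moved the same way, and the longest run held 13. When the calls were shuffled 200 times, at most 100 genes stood in such runs. The median change over all genes was a fall by 0.40 on this scale. With arrays centred on their median instead, 534 genes rose and 490 fell (440 and 522 with quantile normalization), and the changes of the 4 genes named above became 7.20, 7.17, -3.73 and -3.58. With the slide as a block, or with the 2 controls of the same slide alone, the count was 1151.

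At 30 min, 339 genes rose and 833 fell. ABO_2431 was again among the largest rises, by 6.42 ± 0.33 (adjusted p of 5.7e-15), and ABO_2215 rose by 6.16 ± 0.22 (adjusted p of 5.3e-18). ABO_2532 fell by 5.27 ± 0.21, further than at 15 min, and ABO_0745 fell by 5.19 ± 0.14 (adjusted p of 3.6e-17 and 1.8e-20). Rises in common with 15 min numbered 251 and falls 514, with 4 genes moving in opposite directions. Lists of these lengths that were independent would share 47.1 rises and 231.8 falls. Across genes, which are not independent replicates, the changes at the 2 times had a correlation of 0.833 and a covariance of 1.618, where unchanged groups simulated against shared controls gave 0.425 and 0.0149. With 2 controls for each time, 253 rises and 509 falls were shared. The median change over all genes was a fall by 0.50. Centring each array on its own median gave 466 rises and 514 falls (427 and 485 with quantile normalization). This centring put the 4 named changes at 6.81, 6.55, -4.88 and -4.79. The count was 1182 with the slide as a block and with same-slide controls.

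At 60 min the response was widest, with 446 genes that rose and 1152 that fell, or 57.8% of the genes tested. ABO_2431 rose by 7.56 ± 0.33 and ABO_1621 by 6.99 ± 0.10, 189-fold and 127-fold (adjusted p of 1.2e-16 and 2.8e-26). ABO_0473 fell by 6.44 ± 0.22 and ABO_0573 fell by 5.76 ± 0.46 (adjusted p of 1.1e-18 and 2.1e-11). ABO_0473 had fallen by only 1.39 ± 0.22 at 15 min and 1.28 ± 0.22 at 30 min. The changes of 800 genes had the same direction at 30 and 60 min, 224 of them rises and 576 falls, against 54.7 and 347.3 for independent lists, and 26 moved in opposite directions. With 2 controls for each time the number was 799. The correlation across genes was 0.699 and the covariance 1.64, against 0.430 and 0.0152 in the simulation. The median change over all genes was a fall by 0.66. Centring each array on its own median gave 751 rises and 696 falls (534 and 589 with quantile normalization). This centring put the 4 named changes at 8.24, 7.67, -5.76 and -5.08. These 3 arrays were the dimmest of the series, and the count was 1603 with the slide as a block and with same-slide controls.

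By 90 min the response had narrowed to 289 rises and 292 falls. ABO_2708 rose by 5.52 ± 1.05 and ABO_2707 by 5.46 ± 0.86, with adjusted p of 6.8e-05 and 5.9e-06. These standard errors include the spread of the hexadecane arrays. Each was 0.05 with the 3 doubtful hexadecane arrays left out, at the same changes. ABO_1002 fell by 4.37 ± 0.13 and ABO_0126 fell by 3.99 ± 0.25, with adjusted p of 7.5e-19 and 9.6e-13. With 60 min, 151 rises and 210 falls were shared, against 46.7 and 121.7 for independent lists, and 44 genes moved in opposite directions. The correlation across genes was 0.498 and the covariance 0.826, against 0.433 and 0.0152 in the simulation, and with 2 controls for each time 355 genes were shared. Of the 580 changed genes with a locus tag, 154 stood in runs of at least 4 consecutive numbers, against at most 13 in 200 shuffles. The median change over all genes was 0.04, and the count was 582 with the slide as a block and with same-slide controls.

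**Figure D2:**
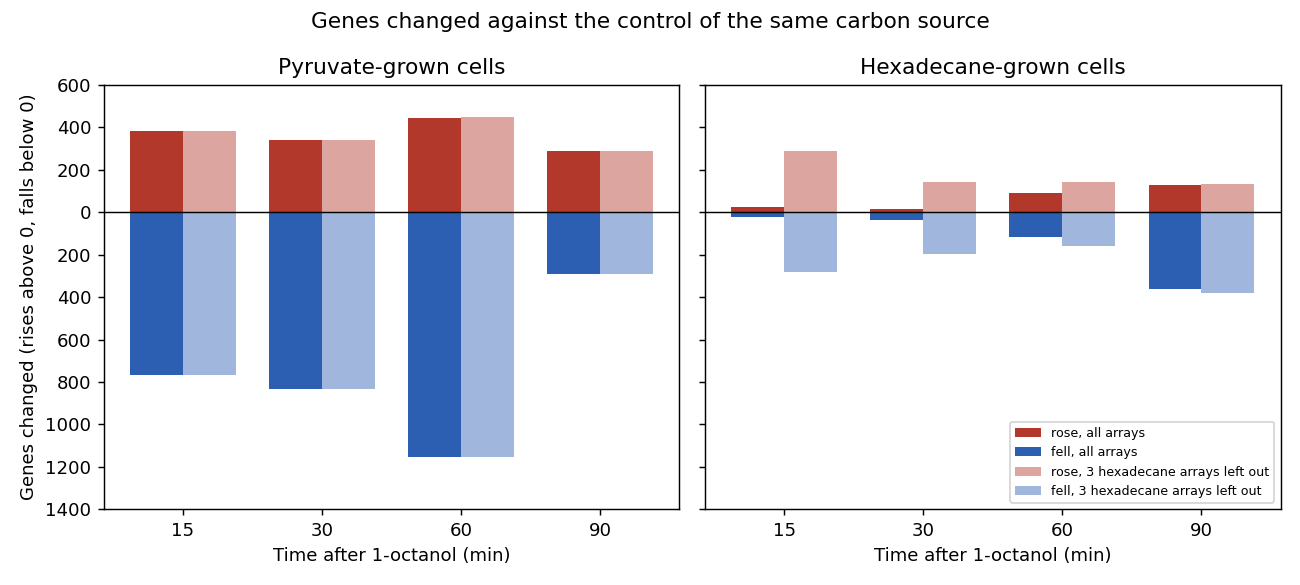
Number of genes that rose (above 0) and fell (below 0) against the control of the same carbon source, by time after 1-octanol in min, with all arrays (solid bars) and with 3 hexadecane arrays left out (pale bars). Pyruvate counts peaked at 60 min with 446 rises and 1152 falls, and leaving out the 3 arrays raised the hexadecane total at 15 min from 45 to 568.

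Over the 4 times, 2157 genes of pyruvate-grown cells, or 78.1% of those tested, changed at least once. Of these, 119 rose at every time and 145 fell at every time (90 with median centring). Both a rise and a fall, at different times, were called for 112 genes. A direct comparison of 90 with 15 min called 656 genes higher and 299 lower at 90 min (3 arrays against 3). Of the 384 genes raised at 15 min, 224 were lower at 90 min than at 15 min and 8 were higher, while 150 were still raised against the control. Of the 769 genes lowered at 15 min, 399 were higher at 90 min than at 15 min and 228 were still lowered. ABO_2016 rose by 4.02 ± 0.58 and ABO_1559 by 3.94 ± 0.43 from 15 to 90 min (adjusted p of 1.1e-06 and 1.4e-08). ABO_0145 fell by 5.41 ± 0.11 and ABO_2215 fell by 5.10 ± 0.24 (adjusted p of 3.3e-22 and 1.5e-15). The median change over all genes from 15 to 90 min was a rise by 0.32. Centring each array on its own median turned the balance, to 355 genes higher and 504 lower (381 and 376 with quantile normalization). This centring put the 4 named changes at 3.63, 3.54, -5.81 and -5.50. The 2 times lay on different slides, and with the slide as a block, which links them through the controls, the count was 966.

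**Figure D3:**
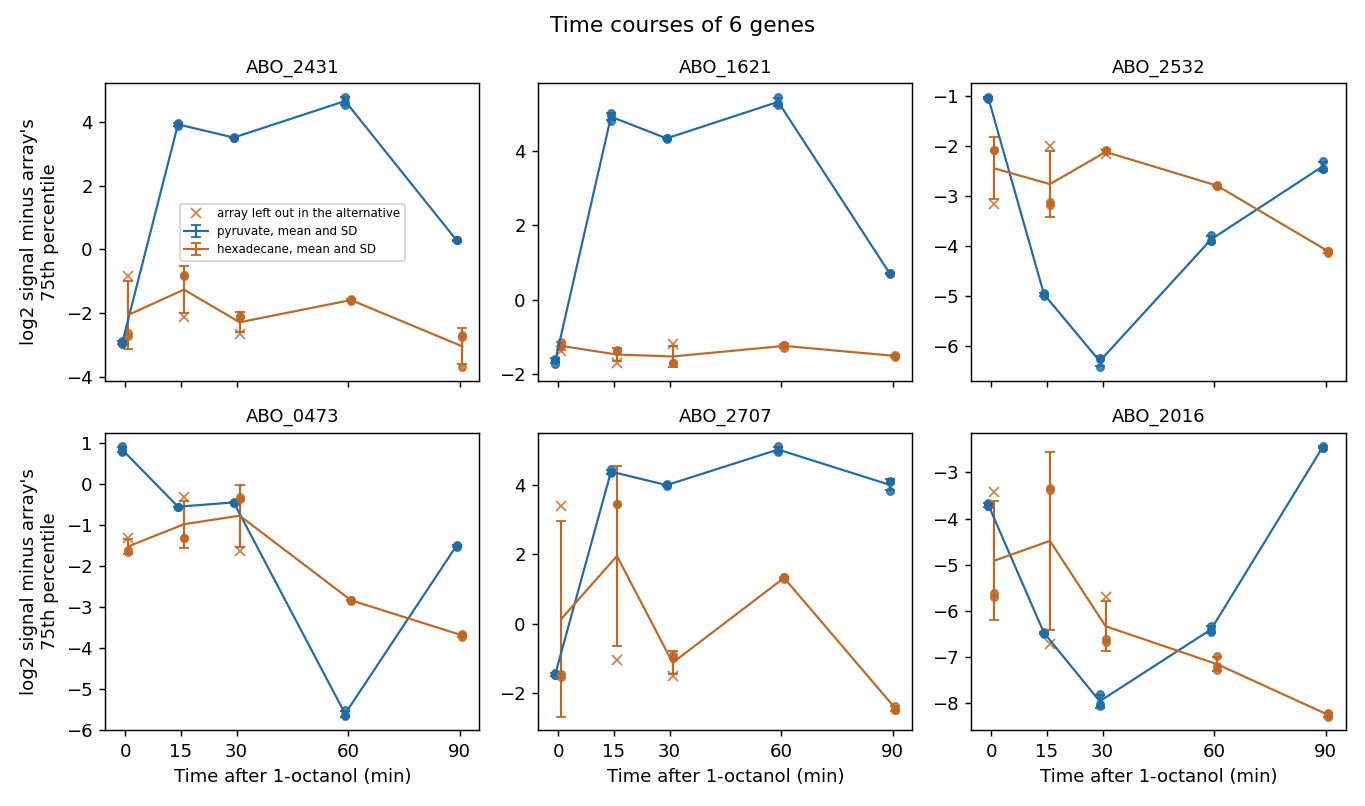
log2 signal minus the 75th percentile of the array for 6 genes named in the text, against time after 1-octanol in min, with pyruvate in blue and hexadecane in orange. Points are arrays, lines and bars are the mean and SD of each group with 3 or 4 arrays, and crosses are the 3 hexadecane arrays left out in the alternative. ABO_2431 stood at -2.92 in the pyruvate control and at 4.64 at 60 min, while its hexadecane means ran from -3.04 to -1.26.

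The same question was asked of hexadecane-grown cells, where the arrays labelled 15 min gave 23 rises and 22 falls against the arrays labelled control (3 against 3). ABO_1069 had the largest change of all, a rise by 1.89 ± 0.62, and ABO_1647 rose by 1.78 ± 0.51. ABO_2401 fell by 1.25 ± 0.30 and ABO_2402 fell by 0.91 ± 0.27, the latter past the adjusted p but under the minimum change. Each of the 4 had an adjusted p of 0.042. Centring on the median gave 35 rises and 17 falls, and quantile normalization 49 and 30. With the 3 doubtful arrays left out, 288 genes rose and 280 fell, all 45 first calls among them in the same direction. The 4 named changes were then 3.63, 2.53, -1.84 and -1.28, and 88 genes stood in runs of at least 4 consecutive tags, against at most 13 in 200 shuffles; with all arrays 0 genes did. The first count rested on single arrays: it was 355 without control replicate 1, 218 without 15 min replicate 3, and 0 without any one of the other 4 arrays (limma; 447 to 1060 genes at an unadjusted p under 0.05). In those 4 fits the adjusted p of the 4 named genes was 0.075 to 0.3, with larger standard errors. The changes were 1.83 to 1.34 for ABO_1647, 1.65 to 1.23 for ABO_1069, -1.21 to -0.97 for ABO_2401 and -0.94 to -0.70 for ABO_2402. With the slide as a block the count was 0 (795 unadjusted), and the changes of ABO_1069, ABO_1647, ABO_2401 and ABO_2402 shrank to 0.82, 1.19, -0.91 and -0.62 (adjusted p of 0.15). On the first hexadecane slide, whose only control was the doubtful replicate 1, the changes of these genes were -0.03, 0.05, -0.43 and -0.03. The second slide held a lone control and a lone array at 15 min, the doubtful replicate 3. In fits within a slide, a lone array of a group was assumed to vary like the other groups.

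At 30 min, 16 genes of hexadecane-grown cells rose and 37 fell. ABO_1133 rose by 1.15 ± 0.37 and ABO_1701 by 1.09 ± 0.37 (adjusted p of 0.038 and 0.039), and ABO_2451 fell by 1.37 ± 0.41 (adjusted p of 0.038). The largest value of all, -1.97 ± 1.12 for ABO_2708, did not pass the test (adjusted p of 0.16) and was -0.15 without the 3 doubtful arrays. Without those arrays there were 144 rises and 199 falls, which kept 51 of the 53 calls, and the other 3 named changes were 1.27, 0.96 and -2.01. The first count was 287 without 30 min replicate 3, 91 without control replicate 2, and 0 without control replicate 3 or 30 min replicate 1 or 2 (limma; 547 to 1387 genes at an unadjusted p under 0.05). The changes of ABO_1133, ABO_1701 and ABO_2451 were 1.27, 1.31 and -1.37 without control replicate 3, at an adjusted p of 0.052 and with larger standard errors (0.42, 0.41 and 0.47). Without 30 min replicate 1 they were 0.92, 0.97 and -1.05 (adjusted p of 0.24), and without replicate 2 they were 0.97, 0.95 and -1.04 (adjusted p of 0.23). Without control replicate 1, ABO_1133 was at 0.87 and ABO_1701 at 0.69 (adjusted p of 0.078 and 0.13). With the slide as a block the count was 0 (125 unadjusted) and the changes of ABO_1133, ABO_1701 and ABO_2451 shrank to 0.45, 0.47 and -0.78 (adjusted p of 0.3). The count was 72 against the 1 control of the same slide.

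At 60 min, 91 genes rose and 117 fell with hexadecane. ABO_2270 rose by 3.39 ± 0.32 and its neighbour in number, ABO_2271, by 2.73 ± 0.33 (adjusted p of 7.0e-09 and 4.0e-07). ABO_2469 fell by 2.38 ± 0.21 and ABO_2016 fell by 2.24 ± 0.58 (adjusted p of 1.7e-09 and 0.0026). Leaving out the 3 doubtful arrays gave 141 rises and 159 falls, with 161 of the 208 calls kept. The changes of these genes were then 3.95, 3.35, -2.76 and -1.50. With only the groups compared in the fit, the adjusted p of ABO_2016 was 0.0504 at the same change, with a standard error of 0.64. The count was 312 with the slide as a block and 301 against the 1 control of the same slide.

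At 90 min, 129 genes rose and 362 fell, the most of the 4 times as labelled. Without the 3 doubtful arrays the order changed, with totals of 568, 343, 300 and 513 at the 4 times, the most at 15 min. With all arrays, ABO_1620 rose by 3.19 ± 0.59 at 90 min and ABO_0591 by 3.08 ± 0.36 (adjusted p of 6.3e-05 and 1.0e-07). ABO_2016 fell by 3.35 ± 0.58 and ABO_2665 fell by 2.84 ± 0.09 (adjusted p of 2.4e-05 and 1.3e-17). Of the genes changed at 60 min, 34 rises and 84 falls were shared with 90 min, where independent lists would share 4.2 and 15.3. The correlation across genes was 0.657 and the covariance 0.290, against 0.497 and 0.0198 in the simulation of shared controls. With each time set against the 1 control of its own slide, so that no control was shared, 60 rises and 100 falls were in common, against 7.6 and 21.4. Without the 3 doubtful arrays the shared numbers were 57 and 106. The other pairs of times shared few genes as labelled: 1 with the same direction and 0 with opposite directions for 15 and 30 min, 3 and 8 for 30 and 60 min, and 6 and 6 for 15 and 90 min, with correlations of 0.189, -0.060 and -0.159 (0.501, 0.491 and 0.491 in the simulation) and covariances of 0.034, -0.015 and -0.051 (0.0199, 0.0196 and 0.0197). Without the 3 doubtful arrays these numbers were 103 and 12, 43 and 22, and 98 and 34, with correlations of 0.332, 0.150 and 0.191. The hexadecane controls as labelled spread more widely than the pyruvate controls, which the simulation did not allow for. The covariance of 0.034 for 15 and 30 min is therefore no sign of a shared response. For 90 min alone, leaving out the 3 doubtful arrays gave 133 rises and 380 falls. Of the 491 calls 387 were kept, and the named changes were 4.01, 3.55, -2.60 and -2.80. With all arrays, the median change over all genes at 90 min was a fall by 0.12. Centring each array on its own median gave 204 rises and 274 falls (223 and 266 with quantile normalization). The named changes were then 3.34, 3.23, -3.19 and -2.68. The count was 524 with the slide as a block and 526 against the 1 control of the same slide.

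From 15 to 90 min, 268 genes rose and 460 fell in hexadecane-grown cells. ABO_0826 rose by 3.12 ± 0.68 and ABO_1620 by 2.55 ± 0.59 (adjusted p of 0.00032 and 0.00057). ABO_2707 fell by 4.4 ± 0.92 and ABO_2619 fell by 4.00 ± 0.63 (adjusted p of 0.00019 and 5.4e-06). With the doubtful arrays left out, 826 genes changed, and the named changes were 4.28, 1.41, -5.89 and -4.96. With only the groups compared in the fit, the adjusted p of ABO_1620 was 0.0747 at the same change, with a standard error of 0.98. Of the 288 genes then raised at 15 min, 202 were lower at 90 min and 31 were still raised; 10 genes rose and 11 fell at all 4 times, against 0 and 0 with all arrays. Median centring gave 353 rises and 386 falls, and quantile normalization 376 and 382; the count was 571 with the slide as a block.

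Before any alcohol was added, hexadecane-grown and pyruvate-grown cells differed in 878 genes, of which 398 were higher and 480 lower with hexadecane (3 arrays against 4). ABO_0961 was higher by 5.86 ± 0.32 and ABO_0395 by 5.10 ± 0.11, 58.1-fold and 34.3-fold (adjusted p of 4.9e-14 and 1.3e-21). ABO_1594 was lower, with a difference of -5.13 ± 0.09, and so was ABO_2604, at -4.36 ± 0.24 (adjusted p of 2.3e-23 and 5.4e-14). Of the 875 differing genes with a locus tag, 84 stood in runs of at least 4 consecutive numbers, against at most 32 in 200 shuffles. With the 3 doubtful arrays left out, 482 were higher and 540 lower, 826 of the 878 calls were kept, and 142 genes stood in such runs, against at most 50. The named differences were then 6.38, 5.27, -5.07 and -4.36. The carbon sources shared no slide, so each slide was treated as a random block (correlation 0.796), which gave 833 genes; slide and carbon source cannot be told apart beyond that.

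The response to the alcohol was compared directly between carbon sources, as the change with hexadecane minus the change with pyruvate. At 15 min this difference was above 0 for 717 genes and below 0 for 389. It was 3.99 ± 0.25 for ABO_0064 and 3.73 ± 0.23 for ABO_1342, and -6.82 ± 0.14 for ABO_1621 and -6.64 ± 0.19 for ABO_1044 (adjusted p of 8.0e-13, 4.1e-13, 6.8e-22 and 3.8e-19). ABO_1621, which rose by 6.59 ± 0.10 with pyruvate, had a change of -0.23 ± 0.10 with hexadecane (adjusted p of 0.094). At 30 min the difference was above 0 for 840 genes and below 0 for 370. It was 5.60 ± 0.31 for ABO_2532 and 4.79 ± 0.21 for ABO_0745, and -6.91 ± 0.33 for ABO_2215 and -6.71 ± 1.26 for ABO_2707 (adjusted p of 5.1e-14, 4.7e-16, 2.9e-15 and 5.3e-05). Leaving out the 3 doubtful arrays gave totals of 1265 at 15 min and 1261 at 30 min in place of 1106 and 1210. The 8 differences were then 4.54, 4.24, -6.78, -6.26, 5.26, 4.35, -7.04 and -4.90. With the slide as a block the totals were 1129 and 1172, and with same-slide controls 1155 (1189 on the second hexadecane slide) and 1203.

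At 60 min, 1166 genes had a difference above 0 and 482 below 0. ABO_2142 differed by 6.29 ± 0.48 and ABO_0573 by 6.0 ± 0.67, ABO_2431 by -7.09 ± 0.48 and ABO_1621 by -6.99 ± 0.14 (adjusted p of 1.6e-11, 1.6e-08, 1.6e-12 and 1.9e-22). At 90 min the balance was the opposite, with 475 above 0 and 700 below. ABO_1731 differed by 5.26 ± 0.39 and ABO_1002 by 4.88 ± 0.19, ABO_2707 by -8.04 ± 1.26 and ABO_2708 by -7.42 ± 1.54 (adjusted p of 2.0e-11, 1.2e-16, 4.9e-06 and 1.6e-04). With the 3 arrays left out the totals were 1635 and 1172 in place of 1648 and 1175, and the 8 differences were 6.98, 5.07, -6.48, -7.05, 4.70, 4.64, -6.41 and -5.55. The totals were 1649 and 1178 with the slide as a block and 1632 and 1180 with same-slide controls. The share of positive differences was 64.8%, 69.4%, 70.8% and 40.4% at the 4 times in order of time, and 48.5%, 50%, 47.1% and 51.5% with median centring (55%, 54.6%, 51.9% and 51.4% with quantile normalization). The median of the differences over all genes was 0.37, 0.51, 0.69 and -0.22. With each array centred on its own median, the named differences were 3.69, 3.43, -7.12 and -6.93 at 15 min. They were 5.21, 4.41, -7.30 and -7.10 at 30 min. At 60 min they were 5.60, 5.30, -7.79 and -7.69, and at 90 min 5.46, 5.09, -7.84 and -7.22.

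The genes changed in both carbon sources were counted at each time and set against independent lists (Fisher's exact test, two-sided, 8 tests over genes that are not independent). At 15 min, 6 rises and 9 falls were shared, against 3.2 and 6.1 (p of 0.12 and 0.23, adjusted 0.19 and 0.27). At 30 min these were 2 and 17, against 2 and 11.2 (p of 1 and 0.046, adjusted 1 and 0.12). At 60 min they were 9 and 61, against 14.7 and 48.8 (p of 0.11 and 0.021, adjusted 0.19 and 0.084), with 65 genes moving in opposite directions. At 90 min they were 9 and 15, against 13.5 and 38.3 (p of 0.24 and 3.7e-06, adjusted 0.27 and 3.0e-05), and 70 genes moved in opposite directions. Without the doubtful arrays, more falls were shared than in independent lists at 15, 30 and 60 min: 126 against 77.9, 83 against 60 and 98 against 66.5 (p of 9.2e-11, 0.00039 and 3.1e-07, adjusted 7.4e-10, 0.001 and 1.2e-06). At 90 min, 30 were shared against 40.3 (p of 0.072, adjusted 0.12). Shared rises were then 54 against 40.1 at 15 min (p of 0.015, adjusted 0.03), and 21, 21 and 12 against 17.7, 22.9 and 13.9 at the later times (adjusted p of 0.48, 0.73 and 0.73). Across genes, which are not independent replicates, the correlation of the changes was 0.196, 0.017, -0.004 and -0.216 at the 4 times. It was 0.193, 0.077, 0.072 and -0.086 without those arrays.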

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

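The tests by which the 3 patterns below are weighed were chosen after the result had been seen, although the slide as a block was a planned setting. The differences in response, same-slide controls and the counts over other splits of the arrays were planned.

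The response to the alcohol differed between carbon sources by a test of the difference itself. As hexadecane minus pyruvate, 1106 genes differed at 15 min, 1210 at 30 min, 1648 at 60 min and 1175 at 90 min. The largest differences at 15 min were 3.99 (ABO_0064), 3.73 (ABO_1342), -6.82 (ABO_1621) and -6.64 (ABO_1044). At 30 min they were 5.60 (ABO_2532), 4.79 (ABO_0745), -6.91 (ABO_2215) and -6.71 (ABO_2707). At 60 min they were 6.29 (ABO_2142), 6.0 (ABO_0573), -7.09 (ABO_2431) and -6.99 (ABO_1621). At 90 min they were 5.26 (ABO_1731), 4.88 (ABO_1002), -8.04 (ABO_2707) and -7.42 (ABO_2708). These ranks hold with all arrays. Without the 3 doubtful arrays ABO_2707 at 30 min was at -4.90 and ABO_2708 at 90 min at -5.55, and genes not listed here ranked above them. Of the 700 splits of the arrays within both carbon sources, 100 were run. At 15 min 2 and at 30 min 2 gave as many genes as the real one, itself included, and 1 did at 60 and at 90 min. Splits that mix the pyruvate arrays also break up the large pyruvate response. This small share therefore does not exclude chance for the difference in response. Both carbon sources were regrouped at once, so these counts do not test the hexadecane labels on their own, and replicates that are not separate cultures would leave chance between cultures untested. The highest of the other splits gave 1397, 1245, 1568 and 815 genes. The split with 1397 set hexadecane control replicate 1 and 15 min replicates 1 and 2, which share a slide, against the other 3 hexadecane arrays. With the slide as a block the count at 15 min was 1129. None of 22 named genes had a pyruvate control array far from the other 3.

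The first pattern weighed was that 3 hexadecane arrays lay nearer to another label than to their own. Mislabelled samples would put each beside the arrays of 1 other label within the differences seen between replicates; the largest such difference was 0.057, against at most 0.059 within the other 7 groups, and the 3 arrays would complete a cycle of 3 labels. The slide alone was argued against by 30 min replicate 3, which differed by at least 0.414 from the 30 min arrays of its own slide. For the other 2 arrays, a shift of a whole slide would leave control and 15 min arrays equally far apart on both slides that hold them, but the difference was 0.424 on the second slide and at most 0.045 on the first. Slide positions went the same way. All 4 pyruvate arrays in the first column of a slide were labelled control, and 30 min replicate 3 was the only hexadecane array there with another label. Exchanging the labels would make it a control. Mislabelling is therefore a candidate explanation that stays open, and no biological explanation was tested. While it stays open, the hexadecane counts at 15 and 30 min as labelled cannot be read as the response at those times.

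The second pattern was the excess of falls over rises with pyruvate. At 30 min the 75th percentile of the signal lay within the range of the controls while the array medians lay at -1.768 or lower relative to it, against -1.397 or higher in the controls, which argues against dim arrays there. At 15 min (-1.732) and 60 min (-2.044) the arrays were also dimmer than the controls, and dimness and time cannot be told apart. Centring on the median brought the rises at 30 min from 28.9% to 47.6% of changed genes, but that setting fixes the balance itself. Without a reference outside the genes, it cannot be told apart whether most transcripts fell or a minority rose, and both may have happened.

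The third pattern was the smaller number of genes changed with hexadecane at 15, 30 and 60 min. The 3 doubtful arrays were not the whole of it: without them the hexadecane count nearest to that of pyruvate was 568 against 1154, at 15 min. At 30 and 60 min the pyruvate counts were 3.42 and 5.35 times the hexadecane counts. Concentration, slides and carbon source changed together and cannot be told apart, although 1649 genes still differed in response at 60 min with the slide as a block. Whether the tested difference in response belongs to the carbon source, the concentration or the slides stays open. A part of time alone stays open too, since no untreated arrays were taken at the later times.

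For the counts against controls with pyruvate, 1 of 35 splits was as large at each time, the real one. The counts were 1153, 1172, 1598 and 581, and the highest of the other splits gave 790, 822, 1256 and 357. For the difference between the carbon sources 1 of 35 was as large too (878 against 551). This is the smallest share that 35 splits can give, and replicates this alike reach it readily. It speaks to the grouping of these arrays alone. Chance between cultures is not excluded if the replicates were technical, and the carbon sources shared no slide. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real values and the highest others were 45 and 486 (4 splits as large) for hexadecane at 15 min, 53 and 230 (3 as large) at 30 min, 208 and 76 at 60 min, and 491 and 0 at 90 min (1 as large in both). They were 955 and 0 for pyruvate 90 against 15 min and 728 and 155 for hexadecane 90 against 15 min. The split with 486 genes set the 3 arrays of the first hexadecane slide against the others, which points to a structure of the samples, as does that with 230, which set control replicate 1 and 30 min replicates 1 and 2 against the rest. Within slides, the comparisons at 15 and 30 min rested on lone controls. The doubtful arrays entered them: control replicate 1 on the first slide, and 15 min replicate 3 and 30 min replicate 3 on the second.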

How the results depend on the processing

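Median centring and leaving out 3 hexadecane arrays together were chosen after the data had been seen. Counts of changed genes stayed within 1.5 times under quantile normalization (14 of 15), normexp, the authors' value table, both filters, the median or brightest probe, another model of the spread and median centring (each 15 of 15); the looser filter removed no gene and so tested nothing. The values of named genes, those ranked but not printed included, kept direction and call in 936 cases under these and the other settings and lost the call in 38, of which ABO_2016 at 60 min and ABO_1620 for 90 against 15 min, both with only the groups compared, lay outside hexadecane at 15 and 30 min. ABO_1069 at 15 min with hexadecane went from 1.89 to -0.03 ± 0.46 with same-slide controls, which is no change within its standard error. The only control there was the doubtful replicate 1. ABO_2708 at 30 min passed the test only with the 3 arrays left out. Leaving out single arrays left direction and call as they were in 469 cases and ended 35 calls, all of hexadecane at 15 or 30 min. Overlaps, runs, time patterns and correlations moved in 136 cases and stayed in 571 under the other settings. Leaving out single arrays moved 111 and left 1160, the moves being in 14 results that involve hexadecane arrays. Dropping the fold minimum raised all 15 counts by its own construction, 13 of them by over 1.5 times. In order of time these became 2175, 2186 and 1761 with pyruvate at 15, 30 and 90 min, 657, 834, 1305 and 1708 with hexadecane, 2003 and 1944 for 90 against 15 min with pyruvate and hexadecane, 2071 between carbon sources, and 1861, 1985 and 1963 for the differences in response at 15, 30 and 90 min; the others, at 60 min, became 2364 with pyruvate and 2201 for the difference in response.

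The other counts that moved were those of hexadecane at 15 and 30 min. Within single slides these rested on lone arrays of a group and on doubtful arrays. At 15 min, 45 genes became 79 with quantile normalization, 564 with array weights, 568 with the 3 arrays left out, 349 on the second slide, and 0 with only the groups compared, the slide as a block, same-slide controls and an adjusted p under 0.01 (limma; 58, 795, 9 and 1210 genes at an unadjusted p under 0.05). At 30 min, 53 became 321 with array weights, 343 with the 3 arrays left out, and 0 with only the groups compared, the slide as a block and an adjusted p under 0.01 (170, 125 and 1332 unadjusted). With only the groups compared, the changes of the named genes at both times stayed as they were while their standard errors rose (adjusted p of 0.72 at 15 min and 0.52 at 30 min), whereas with the slide as a block the changes shrank, as ABO_1133 from 1.15 to 0.45. Leaving out single arrays gave 0 (without 15 min replicate 1 or 2, or control replicate 2 or 3) to 355 (without control replicate 1) at 15 min, and 218 without 15 min replicate 3. At 30 min it gave 0 (without 30 min replicate 1 or 2, or control replicate 3) to 287 (without 30 min replicate 3), and 91 without control replicate 2. The cause was not tested beyond the comparison of the arrays themselves.

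Same-numbered arrays were not alike throughout: correlations of their deviations ran from -0.707 to 0.716, and 10 of 30 were over 0.1. The array of another group whose deviations from its group mean correlated best had the same number for 13 of 15 pyruvate and 9 of 15 hexadecane arrays, a hint from the data, not the design. For treated pyruvate arrays the number also went with the slide column, so number and position cannot be told apart there. With the replicate block, the hexadecane count at 30 min was 0 (1276 unadjusted), with the changes of ABO_1133, ABO_1701 and ABO_2451 still 1.15, 1.09 and -1.37 at an adjusted p of 0.075 and slightly larger standard errors, and that at 15 min was 49, and the other counts moved by less than 1.5 times; with the replicate block and the slide both were 0 (969 and 50 unadjusted). No replicate block could be fitted between carbon sources. The gene list alternatives were not run. Low signal limited little, since 2725 of 2763 genes were well above background on all arrays.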

Other observations

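The overlap with the difference between carbon sources, the counts of runs, the comparison with duplicate spots, the slide columns and all values with 3 hexadecane arrays left out were chosen after the data had been seen. The differences in response and the count with the authors' value table were planned.

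The genes that changed after the alcohol was added to pyruvate-grown cells overlapped with those that differed between the carbon sources. At 30 min, 105 genes rose and were higher with hexadecane, and 225 fell and were lower, against 48.8 and 144.7 for independent lists; with 2 different pyruvate controls for each comparison the numbers were 105 and 227. At 15 min they were 91 and 156, against 55.3 and 133.6, at 60 min 110 and 246, against 64.2 and 200.1, and at 90 min 89 and 84, against 41.6 and 50.7. Genes that moved in the direction opposite to the difference between carbon sources numbered 155, 96, 165 and 53 at the 4 times in order. The covariance of the changes across genes was 0.448 at 30 min, against 0.0154 from shared controls alone. At the other times it was 0.163, 0.410 and 0.203. The correlation across genes, which are not independent replicates, was 0.110, 0.298, 0.229 and 0.191 at the 4 times in order, where unchanged groups with shared controls gave 0.426, 0.440, 0.428 and 0.424 by simulation. The simulated correlations are those of noise alone, so lower observed values do not mean less overlap than by chance. Without the doubtful hexadecane arrays the observed correlation was 0.052, 0.244, 0.163 and 0.088. The numbers were then 100 and 155 at 15 min, 111 and 238 at 30 min, 120 and 256 at 60 min, and 87 and 68 at 90 min, with 205, 129, 232 and 76 in opposite directions. The lists between carbon sources were then longer, with 482 genes higher and 540 lower, so independent lists would share more as well. That number was not computed without the doubtful arrays, so no excess can be read from these overlaps.

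ABO_2016 stood at -3.70 ± 0.04 (SD, n = 4) in the pyruvate control, reached -7.96 ± 0.14 (n = 3) at 30 min and was back at -2.46 ± 0.02 (n = 3) at 90 min, whereas with hexadecane it stood at -8.26 ± 0.04 (n = 3) at 90 min. Its change of -4.26 at 30 min with pyruvate did not meet the rule for named genes, since no probe was well above background on every array. The level of ABO_2016 there lay near the floor and is uncertain. The difference in its response between carbon sources, hexadecane minus pyruvate, was 3.21 ± 0.79 (SE) at 15 min and -4.59 ± 0.79 at 90 min (limma, adjusted p of 9.9e-04 and 1.7e-05). Without the 3 doubtful arrays it was 5.07 ± 0.09 and -3.85 ± 0.09. ABO_0473 fell in both, to -5.61 ± 0.07 (n = 3) at 60 min with pyruvate and to -3.70 ± 0.03 (n = 3) at 90 min with hexadecane.

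Runs of at least 4 consecutive tags were also counted where the results above do not give them. With pyruvate they held 211 genes at 30 min and 418 at 60 min, against at most 109 and 305 in 200 shuffles, and 118 and 199 with median centring. With hexadecane they held 0 genes at 30 min, 14 at 60 min and 4 at 90 min, against at most 0, 4 and 13. Without the doubtful arrays these were 4, 24 and 0, against at most 5, 4 and 21, so no excess over the shuffles was seen at 30 or 90 min. From 15 to 90 min, runs held 146 genes with pyruvate and 45 with hexadecane, against at most 61 and 26, and 95 with hexadecane, against at most 34, without the doubtful arrays. For the differences in response they held 197, 232, 444 and 184 genes in order of time, against at most 76, 120, 321 and 79, and 161, 144, 288 and 189 with median centring. Without the doubtful arrays they held 227, 213, 380 and 187, against at most 115, 141, 312 and 81. Calls with median centring were not shuffled, so whether their runs exceed chance was not tested.

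Replicate arrays of 7 groups differed by about as much as duplicate spots within an array. The median standard deviation between arrays was 0.78 to 1.45 times that computed from duplicate spots, against 9.35 to 13.27 times in the hexadecane control, 15 min and 30 min groups.

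All 4 pyruvate arrays in the first column of a slide were labelled control. Of the 3 hexadecane arrays in that column, 2 were labelled control and the other was 30 min replicate 3, whereas 1 hexadecane control, replicate 1, lay elsewhere.

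In the authors' value table, 70.0% of the values of hexadecane 15 min replicate 2 were whole numbers exactly, with no tolerance. With that table in place of the scanner values, the count at 15 min was 50 in place of 45.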
